A study of Mus musculus with 9 samples.

How the data were processed

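RNA was measured in 9 samples of lymph node CD4+ T cells from male mice, 5 WT and 4 cKO for Kdm6a. Per the labels, RNA was isolated with a Direct-zol kit and made into stranded libraries with a KAPA kit after mRNA enrichment. The authors deposited 1 table of raw read counts per gene, whole numbers that were not normalized, with 1 column per sample. The submitters' processing notes name bcl2fastq 2.17 and the genome build mm10. The aligner, the counting tool, its strand setting and the gene annotation are not given in the sources used here. Each column was assigned to the sample whose title it matched, and 0 columns belonged to no sample of the series. Every line of the table named a gene.

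The table held 39017 Ensembl gene IDs, of which 13708 had 0 counts in all samples. Symbols were found for 37607 IDs and not for 1410, and 12 IDs that shared a symbol with another were kept as IDs. Positions, GC content and exonic length came from GENCODE M21, on the same build, and may differ from the annotation the authors used. Total counts ran from 20587482 to 26387488 per sample, at which depth 1 CPM corresponds to more than 20 counts. A gene with 0 counts in a library was given an upper limit of 3 counts of its total, which covers counting error only, since reads without molecular identifiers are not independent molecules.

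The samples were compared pairwise before they were averaged. The chi-square per gene between samples of 1 group ran from 3.52 to 22.1, so no 2 samples agreed within sampling noise, and Pearson's r of log2 CPM, across genes that are not independent replicates, ran from 0.991 to 0.995 within and from 0.982 to 0.991 between groups.

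The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the raw counts of all 9 samples, with TMM normalization, genes kept by filterByExpr, no covariate, a two-sided test and Benjamini-Hochberg adjusted p below 0.05 over the 14693 genes tested. The biological coefficient of variation was 8.04%. Fold changes are cKO over WT on the log2 scale with their standard error, and levels are CPM, counts scaled by TMM-adjusted library totals. Log2 CPM used a prior count of 2. The median log2 fold change of all tested genes was 0.0012.

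Gene lists were compared with all other genes by camera of limma 3.58.1 on voom values, with its preset inter-gene correlation of 0.01, adjusted over the 28 lists with at least 3 tested members. The 24 program lists covered H3K27 demethylases, PRC2, the MLL3/MLL4 complex, Th1, Th2, Th17, regulatory and follicular helper T cells, naive and homing genes, T cell activation, inhibitory receptors, T cell receptor signalling, interferon-stimulated genes, innate and NF-kB signalling, adhesion and chemokine receptors, cytotoxic genes, mitosis, DNA replication, glycolysis, oxidative phosphorylation, cholesterol synthesis, apoptosis, p53 targets and sex-linked paralogs. The 10 marker lists covered B, plasma, CD8 T, gamma-delta T, natural killer, macrophage and monocyte, dendritic, neutrophil, erythroid, and stroma and vessel cells. The markers Ighd and Trdc had no matching ID. With a correlation estimated from the data no list was called by camera (2 program lists and 0 marker lists at unadjusted p under 0.05), and fry, which asks whether the genes of a list move on balance in 1 direction, called 6 program lists and 0 marker lists. The 6 included the H3K27 demethylases, which hold the targeted gene Kdm6a.

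The groups, the main test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named the H3K27 demethylases and Cd4, the 12 genes with the largest rise and the 12 with the largest fall among called genes with a mean of at least 1 CPM and no overlap between groups, up to 4 called members of each list with the smallest adjusted p (or, where none was called, up to 2 with the smallest p), and the 2 most abundant tested members of each marker list. Other members are named as part of a list count.

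The alternatives were DESeq2 size factors, upper-quartile scaling, no count filter, a stricter filter of at least 1 CPM in 4 samples, leaving out each sample, 1 surrogate variable from sva 3.50.0, DESeq2 1.42.0, limma-voom with and without sample weights, robust quasi-likelihood, other thresholds, and omission of sex chromosome genes, and for lists an estimated correlation, fry and omission of the top member. Per-library offsets on GC content and exonic length were added after seeing the data.

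The scripts' tests were tested on simulated data with the real means and library sizes, and with dispersions from the fitted trend instead of each gene's own. For edgeR, 200 of 14693 simulated genes were changed, against 15.8% of genes called in the data. The shares recovered therefore need not hold for the data. Of 50 genes changed at each fold, edgeR recovered 32% at 1.2-fold, 68% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, with 5 false calls among 151. With a simulated GC trend and 14693 genes, 1320 unchanged genes were called without the offsets and 8 with them. A simulated shift of the DNA replication list, larger than its observed median of -0.13, was called by camera and 0 other lists were. The simulated genes varied independently of each other, so this could not test camera on lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.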

Results

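RNA-seq counts per gene were examined for CD4+ T cells, the helper lineage of T lymphocytes, taken from lymph nodes of male C57BL/6 mice. The series asked how the expression of other genes depends on Kdm6a, an X-linked gene that encodes a demethylase of histone H3 lysine 27. All 9 samples carried a floxed Kdm6a allele on their X chromosome. The 5 WT samples (replicates 1, 3, 4, 5 and 9) had no Cre, and the 4 cKO samples (replicates 2, 6, 7 and 8) carried CD4-Cre, which drives recombination in cells with Cd4 promoter activity. The labels state no stimulation of the cells, while the name of the deposited table carries the word "stim". Il2ra, a gene induced by T cell activation, was at 3182 CPM in WT and 2569 CPM in cKO. Cd4 was at 873 and 957 CPM. The replication genes named below ran from 117 CPM (Gins2) to 706 CPM (Mcm3) in WT and from 101 to 634 CPM in cKO. These levels argue against resting cells in both genotypes, though no sample of a known state was measured beside them. How the cells were treated is not stated. Total counts per sample ran from 20587482 in cKO 7 to 26387488 in WT 9, with 24016000 ± 2182000 (SD, n = 5) in WT and 22577000 ± 1520000 (SD, n = 4) in cKO, a difference within the spread of the samples (two-sided exact permutation p = 0.302). Nothing in the labels says that the samples came from separate mice, so each p-value measures the spread between these samples, which may be partly technical.

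Kdm6a itself was lower in every cKO sample than in every WT sample. Its level was 62.7 CPM ± 1.59 (SD, n = 5) in WT and 42.7 CPM ± 1.48 (SD, n = 4) in cKO, and it fell by 0.55 on the log2 scale (SE 0.04), which is 31.9% lower (edgeR adjusted p = 2.89e-05). The WT samples 1, 3, 4, 5 and 9 held 62.4, 60.04, 63.8, 63.4 and 63.8 CPM, and the cKO samples 2, 6, 7 and 8 held 41.8, 42.7, 41.5 and 44.8 CPM. Uty, the Y-linked paralog of Kdm6a, rose by 0.24 (SE 0.05), from 36.6 to 43.0 CPM (adjusted p = 0.00695). Kdm6b, the autosomal demethylase of the same residue, was at 113 CPM in WT and 117 CPM in cKO, a log2 difference of 0.05 (SE 0.23, adjusted p = 0.917). Kdm6a (ENSMUSG00000037369) lies on the plus strand of chromosome X from 18162575 to 18279936 of mm10, Uty (ENSMUSG00000068457) on chromosome Y from 1096861 to 1245759, and Kdm6b (ENSMUSG00000018476) on chromosome 11 from 69398508 to 69413675. The counts are sums over whole genes and the labels do not say which exon is floxed, so reads from exons outside the deleted part stay in the Kdm6a value of the cKO samples. With Kdm6a lower, Uty higher and Kdm6b between them, the median and the mean of these 3 genes differed in sign, at 0.05 and -0.09. Camera called no shift (adjusted p = 0.814), while fry gave a downward adjusted p of 0.0216. Since the list holds Kdm6a, the targeted gene, the fry result does not describe the demethylases as a group. The sign of Kdm6b, and with it that of the median, rested on single libraries, with -0.07 without WT 4, -0.06 without WT 9 and 0.34 for Kdm6b (0.25 for the median) without WT 1. Kdm6b was at 0.004 without cKO 2, 0.02 without WT 3 and 0.11 without cKO 7.

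**Figure D1:**
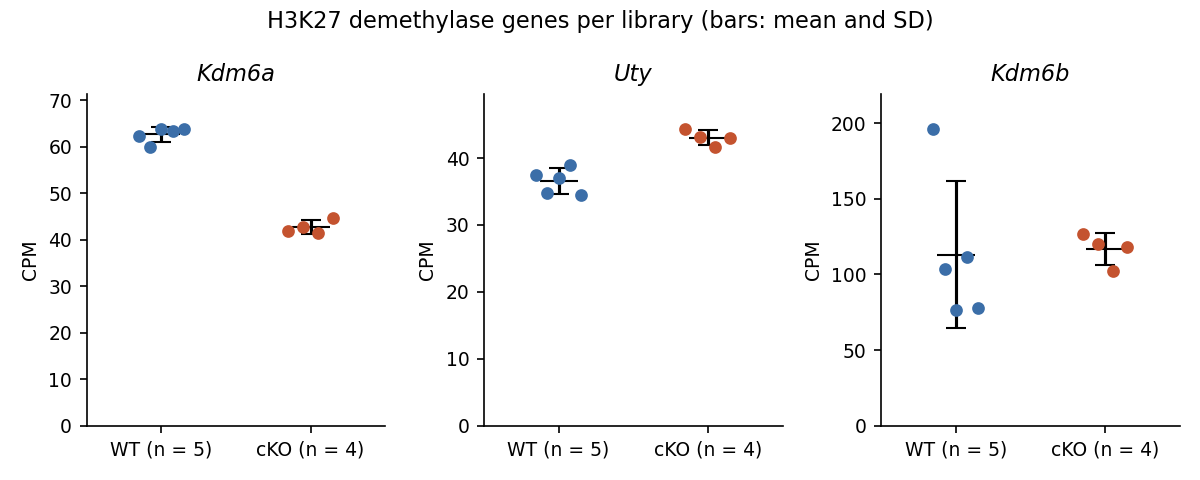
CPM of Kdm6a, Uty and Kdm6b in each library, with WT in blue (n = 5), cKO in red (n = 4) and bars for the mean and SD. Every cKO library lies below every WT library for Kdm6a and above every WT library for Uty, while the Kdm6b values overlap.

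Among the genes with the largest rises were Nrn1, Mmp14, Kit, Fn1 and Hspg2, and among those with the largest falls Igsf23, Cd86, Lair1 and Sytl2. Nrn1, which encodes the GPI-anchored protein neuritin, rose 3.78-fold from 25.96 CPM ± 3.78 (SD, n = 5) to 98.2 CPM ± 19.8 (SD, n = 4), and was the most abundant of the 12 genes with the largest rises. Mmp14, a membrane-bound matrix metalloproteinase, rose 6.60-fold from 0.663 to 4.44 CPM, and Kit, the stem cell factor receptor, rose 3.83-fold from 1.33 to 5.05 CPM. The matrix genes Fn1 (fibronectin) and Hspg2 (perlecan) rose 3.33-fold and 3.79-fold, from 0.756 to 2.53 CPM and from 0.469 to 1.79 CPM. The falls included Cd86, a ligand of the costimulatory receptor CD28, which was 76.2% lower at 2.50 CPM against 10.6 CPM, and Lair1, an inhibitory collagen receptor, which was 74.1% lower. Igsf23, an immunoglobulin superfamily gene, was 79.2% lower at 9.47 CPM ± 2.99 (SD, n = 4) against 45.6 CPM ± 2.41 (SD, n = 5), and Sytl2, a synaptotagmin-like gene of vesicle transport, was 73.8% lower at 5.45 against 20.7 CPM.

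The log2 fold changes were 1.92 (SE 0.14, edgeR adjusted p = 3.05e-05) for Nrn1, 2.72 (SE 0.27, adjusted p = 0.000229) for Mmp14, -2.27 (SE 0.16, adjusted p = 2.89e-05) for Igsf23, -2.07 (SE 0.22, adjusted p = 0.000303) for Cd86 and -1.93 (SE 0.13, adjusted p = 2.89e-05) for Sytl2. Nrn1 lies on chromosome 13 from 36725361 to 36735131, Mmp14 on chromosome 14 from 54431612 to 54445364, Igsf23 on chromosome 7 from 19937305 to 19950756, Cd86 on chromosome 16 from 36603869 to 36666081 and Sytl2 on chromosome 7 from 90302252 to 90410719 of mm10. The other large rises, between 1.61 and 2.82 on the log2 scale, were those of Klra7, Dclk1, Kndc1, Cttnbp2nl, Spry2, Cables1 and Utf1. The other large falls, between -1.90 and -2.90, were those of Cyp11a1, which encodes the enzyme that starts steroid hormone synthesis, Eya2, Gpnmb, 4930486L24Rik, Art4, Ctla2a, Pdlim4 and Sorcs2. Klra7 and Ctla2a belong to families of near-identical genes whose reads the authors' counting could have split, so their values are uncertain, and Klra7 was at 0.284 CPM in WT. Spry2, Cttnbp2nl, Cables1 and Kndc1 were also low in WT, at 0.557, 0.606, 0.779 and 0.869 CPM. The calls of all 24 genes with the largest changes held in each of the 20 other settings that gave a value, with adjusted p up to 0.0410, and the log2 change of Cables1 was 1.08 without cKO 2 against 1.62 with it.

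Across the transcriptome, 2324 of 14693 genes tested passed adjusted p 0.05 in edgeR, 1028 higher and 1296 lower in cKO, and 4572 had an unadjusted p under 0.05. Most of these changes were small. The median fold of the called genes was 1.26, and a fold of at least 2 was reached by 99 higher and 143 lower genes. In 2330 genes, 15.9% of those tested, the values of the 2 genotypes did not overlap, against 1.59% by chance. The first principal component held 42.4% of the variance and separated the genotypes, with WT 1 the nearest of the WT samples to the cKO samples. The count of called genes was 1263 without cKO 6 (531 higher and 732 lower), 1504 without cKO 8 (632 higher) and 1528 without WT 4 (651 higher), and the higher genes numbered 662 without WT 9. With upper-quartile scaling, 54.2% of the called genes were higher, against 44.2% with TMM.

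**Figure D2:**
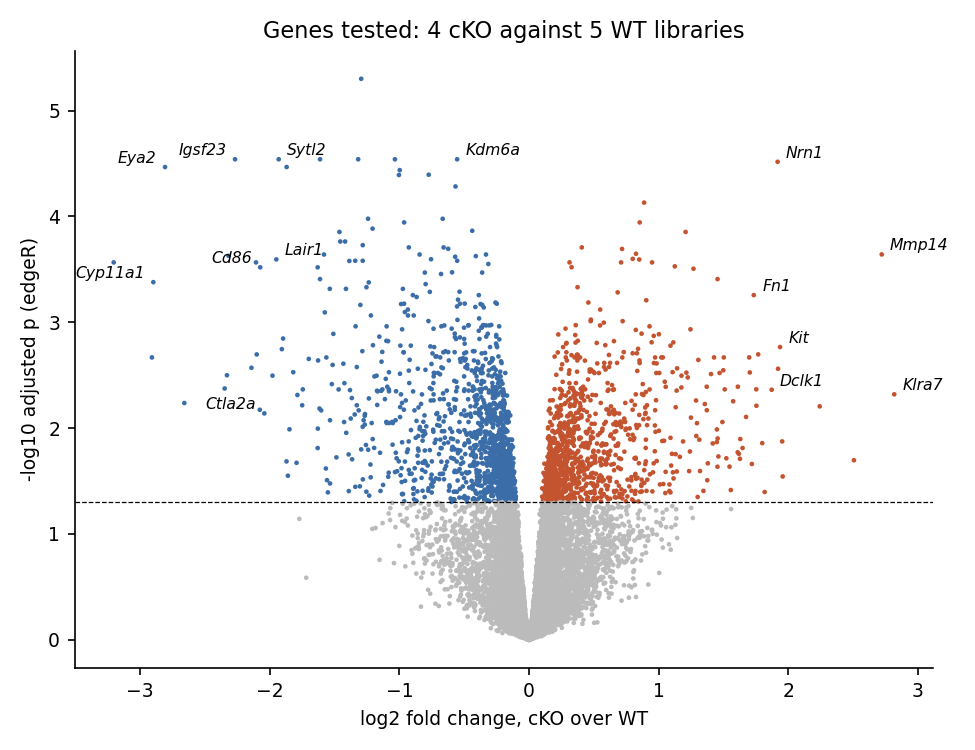
Log2 fold change of cKO over WT against -log10 of the edgeR adjusted p for each of the 14693 genes tested, with called genes in red (1028 higher) and blue (1296 lower), the rest in grey and the dashed line at adjusted p 0.05. Kdm6a and some of the genes with the largest changes are named.

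**Figure D3:**
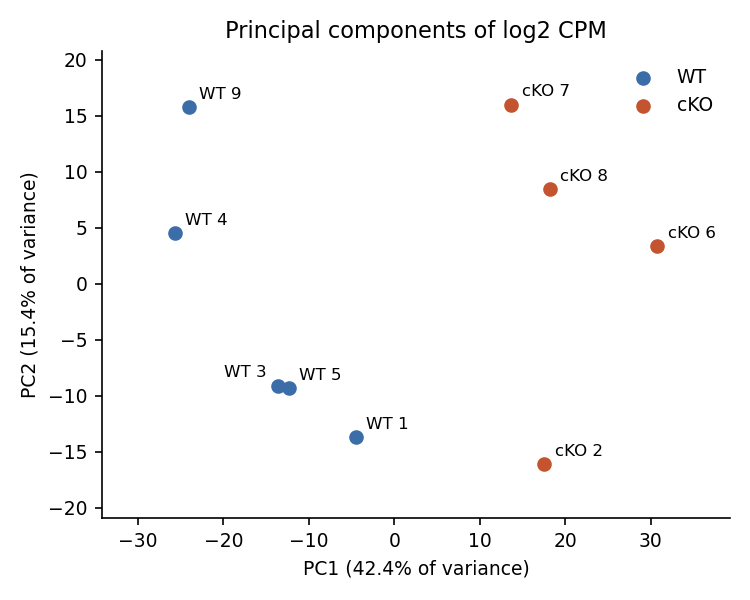
First and second principal components of log2 CPM for the 9 libraries, with WT in blue and cKO in red. All cKO libraries lie to the right of all WT libraries on the first component, which holds 42.4% of the variance.

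Of 13 tested targets of p53, the transcription factor of the DNA damage response, 8 rose, none fell and 5 did not pass the test in edgeR, and 10 rose with the p-values adjusted over the list alone. At unadjusted p under 0.05, 11 were higher and 0 lower, and DESeq2 and limma-voom called 0 lower. Pmaip1 and Bbc3, which encode the pro-apoptotic proteins NOXA and PUMA, rose by 0.91 (SE 0.11, edgeR adjusted p = 0.000620) and 0.72 (SE 0.09, adjusted p = 0.000976) on the log2 scale. Phlda3, a repressor of Akt signalling, rose by 0.73 from 45.7 to 75.9 CPM, and the RNA-binding protein gene Zmat3 rose by 0.54 from 182 to 265 CPM. Plk2, Ccng1, Sesn2 and Mdm2 were the other targets that rose, while Cdkn1a, the cell cycle inhibitor p21, was at 149 CPM in WT and 222 CPM in cKO (adjusted p = 0.0637). The median change of the list was 0.57 (camera adjusted p = 1.49e-07), with adjusted p = 0.452 with an estimated correlation and 0.0143 by fry. Trp53, the gene of p53 itself and chosen after its values were seen, was at 215 and 220 CPM (adjusted p = 0.536). The share of counts from mitochondrial genes, a sign of cell and RNA quality, was also higher in cKO, at 2.59% ± 0.138 (SD, n = 4) against 2.38% ± 0.0573 (SD, n = 5; two-sided exact permutation p = 0.0159). Cre was present in every cKO sample and in no WT sample, and the list level of WT 1, at 0.25, was the highest of the WT samples.

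Other genes of cell death went both ways. Of 16 tested apoptosis genes, 3 rose, 5 fell and 8 did not pass, and 6 rose and 5 fell with the p-values adjusted over the list alone. The receptors of tumour necrosis factor were both lower, Tnfrsf1b at -0.57 (SE 0.05, edgeR adjusted p = 5.22e-05) and Tnfrsf1a at -0.39 (SE 0.06, adjusted p = 0.00243). Pmaip1 and Bbc3, shared with the p53 list, were the largest rises. Camera called no shift of the apoptosis list (adjusted p = 0.928), whose median of -0.01 and mean of 0.03 differ in sign, though the median was 0.006 without cKO 6 and 0.005 with upper-quartile scaling. Without WT 1, 7 apoptosis genes rose, and 3 fell without any 1 of cKO 2, cKO 8, WT 4 or WT 9.

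Of 16 tested genes of DNA replication, 9 fell by small amounts, none rose and 7 did not pass in edgeR (0 higher at unadjusted p under 0.05, and 0 in DESeq2 and limma-voom), and 15 fell with the p-values adjusted over the list alone. The largest falls by adjusted p were those of Gins2, a helicase subunit, at -0.20 (SE 0.04, edgeR adjusted p = 0.00493), the helicase genes Mcm5 and Mcm3 at -0.18 and -0.16, and the sliding clamp gene Pcna at -0.16 (SE 0.03). The median change was -0.13 (camera adjusted p = 1.49e-07), with adjusted p = 0.452 with an estimated correlation and 0.00692 by fry. Genes of mitosis had a median change of -0.13 as well (camera adjusted p = 0.000343), with adjusted p = 0.926 with an estimated correlation and 0.138 by fry. Of the 16 mitosis genes, 3 fell, none rose and 13 did not pass (0 higher at unadjusted p under 0.05, and 0 in DESeq2 and limma-voom), and 8 fell with the p-values adjusted over the list alone. Those 3 were Birc5 (survivin) at -0.23, the mitotic kinase gene Plk1 at -0.21 and the checkpoint kinase gene Bub1 at -0.13. The share of mitochondrial counts moved with genotype here too, at 2.38% in WT and 2.59% in cKO.

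The counts of these lists changed when 1 sample was left out. The median stayed between -0.149 and -0.115 for replication genes and between -0.158 and -0.096 for mitosis genes. The number of replication genes that fell was 5 without cKO 6 and also 5 without cKO 8, and the number of mitosis genes was 8 without WT 1, 1 without cKO 2 or cKO 8, and 0 without cKO 6. DESeq2 called 5 mitosis genes lower. Birc5 lost its call without cKO 6 (edgeR adjusted p = 0.0549), and Bub1 without any 1 of cKO 2, 6 or 8 or WT 5 or 9 (from 0.0505 to 0.0951), with upper-quartile scaling (0.0522) and with no count filter (0.0620). Plk1 lost it without any 1 of cKO 2, 6 or 8 or WT 3 or 4 (from 0.0514 to 0.0791) and after offsets on GC content and gene length (0.0678).

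Of 24 tested integrins, chemokine receptors and related genes of migration and adhesion, 9 fell, 1 rose and 14 did not pass, and 16 fell and 3 rose with the p-values adjusted over the list alone. Itgb3, the integrin beta 3 chain, was 63.7% lower, from 134 to 48.8 CPM (log2 -1.46, SE 0.13, edgeR adjusted p = 0.000140). Itgb7, a chain of gut-homing integrins, was at -0.75 (SE 0.12), the chemokine receptor gene Ccr4 at -0.85 (SE 0.16) and the sphingosine-1-phosphate receptor gene S1pr4 at -0.69 (SE 0.14). Itgb1, the integrin beta 1 chain, was the 1 member that rose, from 201 to 265 CPM. The median change was -0.53 (camera adjusted p = 0.000434), with adjusted p = 0.327 with an estimated correlation and 0.00508 by fry. The number that fell was 6 without WT 4 or cKO 6, 7 with robust quasi-likelihood and 12 without WT 1. The median was -0.37 without cKO 6, -0.39 with a filter of at least 1 CPM in 4 samples and -0.62 without cKO 2. The number that rose was 3 without WT 5, 2 without cKO 7 and 2 of 26 tested with no count filter. Of 26 tested, DESeq2 called 2 higher and 14 lower. The share of mitochondrial counts, 2.38% in WT and 2.59% in cKO, moved with genotype beside this list too.

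**Figure D4:**
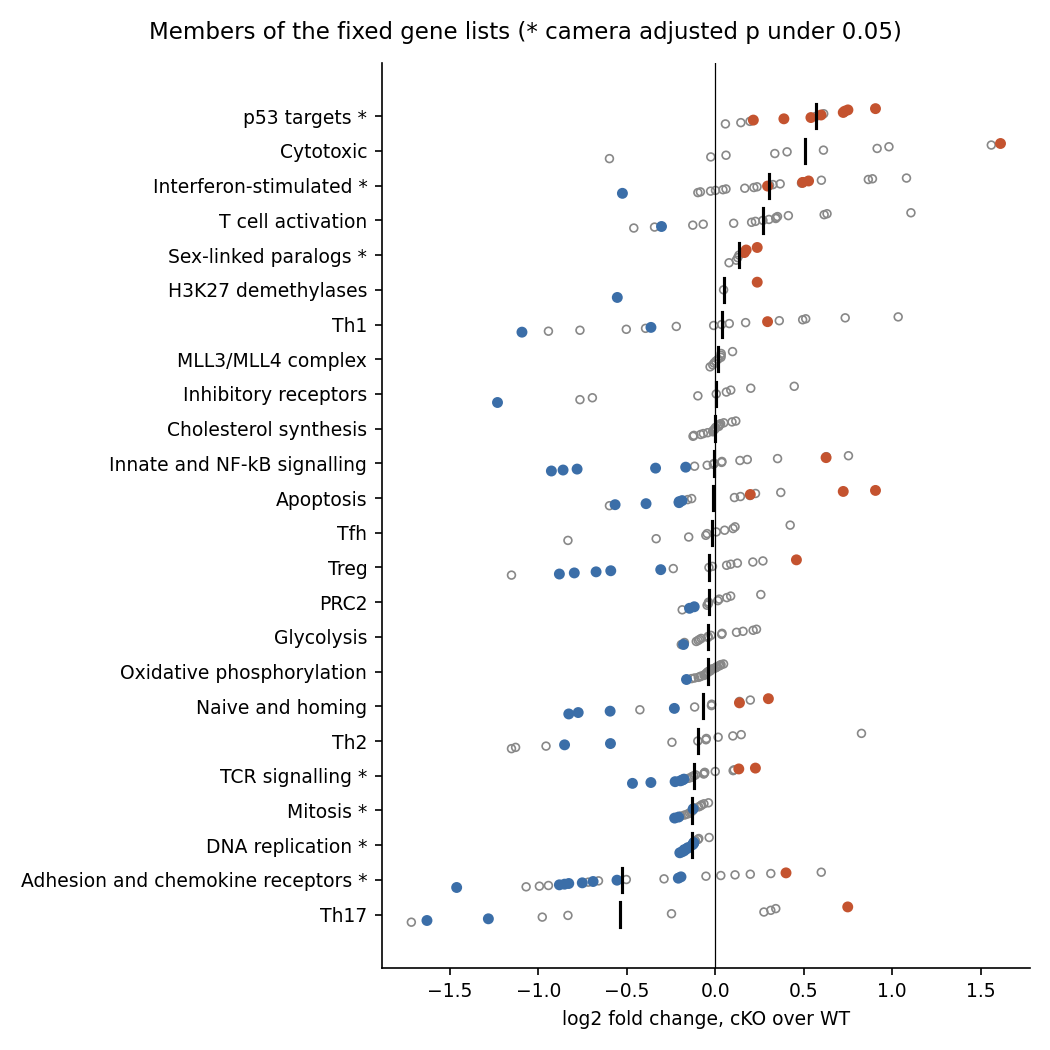
Log2 fold change of each tested member of the 24 fixed gene lists, with filled points for members past adjusted p 0.05 over all genes tested (red higher, blue lower), open points for the rest and a bar at the median. An asterisk marks the 7 lists called by camera at its preset correlation, of which none was called with an estimated correlation.

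Genes of naive T cells and lymph node traffic went both ways. Of 12 tested, 2 rose, 4 fell and 6 did not pass, and 4 rose and 5 fell with the p-values adjusted over the list alone. Foxo1, a transcription factor of T cell quiescence, fell by 0.23 (SE 0.04, edgeR adjusted p = 0.00623), while Bach2, a transcriptional repressor of effector differentiation, rose by 0.30 (SE 0.06, adjusted p = 0.00937). Il7r, the receptor chain for the survival cytokine IL-7, was at -0.59 (adjusted p = 0.0160), and S1pr1, the receptor for lymph node egress, was at -0.83 (adjusted p = 0.0295). Camera called no shift (adjusted p = 0.695). The Il7r call was lost without cKO 6 or cKO 8 (adjusted p = 0.0509 and 0.0516), and the S1pr1 call without any 1 of cKO 2, 6 or 8 or WT 4 or 9 (adjusted p from 0.0594 to 0.0882) and with robust quasi-likelihood (0.0815). The list held 1 gene that fell without cKO 6 or cKO 8, 2 without WT 4 or WT 9, and 1 gene that rose without any 1 of WT 3, WT 4, cKO 7 or cKO 8. With robust quasi-likelihood 2 fell, and 1 rose with no count filter or after GC and length offsets.

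Of 19 tested genes of the T cell receptor complex and its proximal signalling, 6 fell, 2 rose and 11 did not pass, and 9 fell and 2 rose with the p-values adjusted over the list alone. With 1 sample left out, from 4 to 7 fell and from 1 to 2 rose. The count that fell was 4 without any 1 of WT 3, 4, 5 or 9 or cKO 6 or 8. Nfatc2, a calcium-dependent transcription factor, was at -0.47 (SE 0.06, edgeR adjusted p = 0.00107), the adaptor gene Lat at -0.36 (SE 0.05) and the kinase gene Lck at -0.20 (SE 0.04). Cd5, an inhibitory coreceptor, rose by 0.23 (SE 0.03, adjusted p = 0.00130). The median was -0.12 (camera adjusted p = 0.0236), with adjusted p = 0.452 with an estimated correlation, 0.00692 by fry, and 0.0820 by camera without Nfatc2. Mitochondrial counts were again 2.38% of the total in WT and 2.59% in cKO. Cd4, which marks the lineage, was at 0.13 (adjusted p = 0.0480) and lost its call without any 1 of WT 1, 3, 4 or 5 or cKO 6, 7 or 8, with adjusted p from 0.0599 to 0.137, and also with no count filter (0.0760) and with 1 surrogate variable (0.0552).

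Genes induced by T cell activation showed 1 fall, no rise and 16 members that did not pass in edgeR, and 2 rose and 3 fell with the p-values adjusted over the list alone. At unadjusted p under 0.05, 4 were higher and 3 lower. These counts depended on the setting, with 1 higher and 3 lower in DESeq2, 1 and 1 in limma-voom, 3 and 2 in limma-voom with sample weights, 3 and 3 with 1 surrogate variable or with no count filter, and 2 and 1 with upper-quartile scaling. Il2ra, the alpha chain of the IL-2 receptor and also a marker of regulatory T cells, was at -0.31 (SE 0.08, edgeR adjusted p = 0.0190). The median was 0.27, which was 0.45 without WT 1 and 0.15 without cKO 6, and camera called no shift (adjusted p = 0.208). WT 1 stood apart in this list, with a mean log2 level of 0.78 against -0.45 to 0.09 in the other WT samples, and without it 8 members rose and camera called the list higher (adjusted p = 0.00149). In that list 1 rose without cKO 2 and 2 fell without any 1 of cKO 2 or 6 or WT 4, 5 or 9. Of 9 tested inhibitory receptors, 1 fell and 8 did not pass, both over all genes and adjusted over the list alone. That gene was Entpd1, which encodes the ectonucleotidase CD39 and fell by 1.24 (SE 0.14, adjusted p = 0.000420). Camera called no shift of the inhibitory receptors (adjusted p = 0.748), whose median of 0.005 and mean of -0.22 differ in sign. That median was below 0 without any 1 of WT 4, 5 or 9 or cKO 6 (from -0.09 to -0.02), and ran from 0.01 to 0.09 without any 1 of the other libraries. Of these receptors, 1 rose without WT 1 and 2 fell without WT 9.

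**Figure D5:**
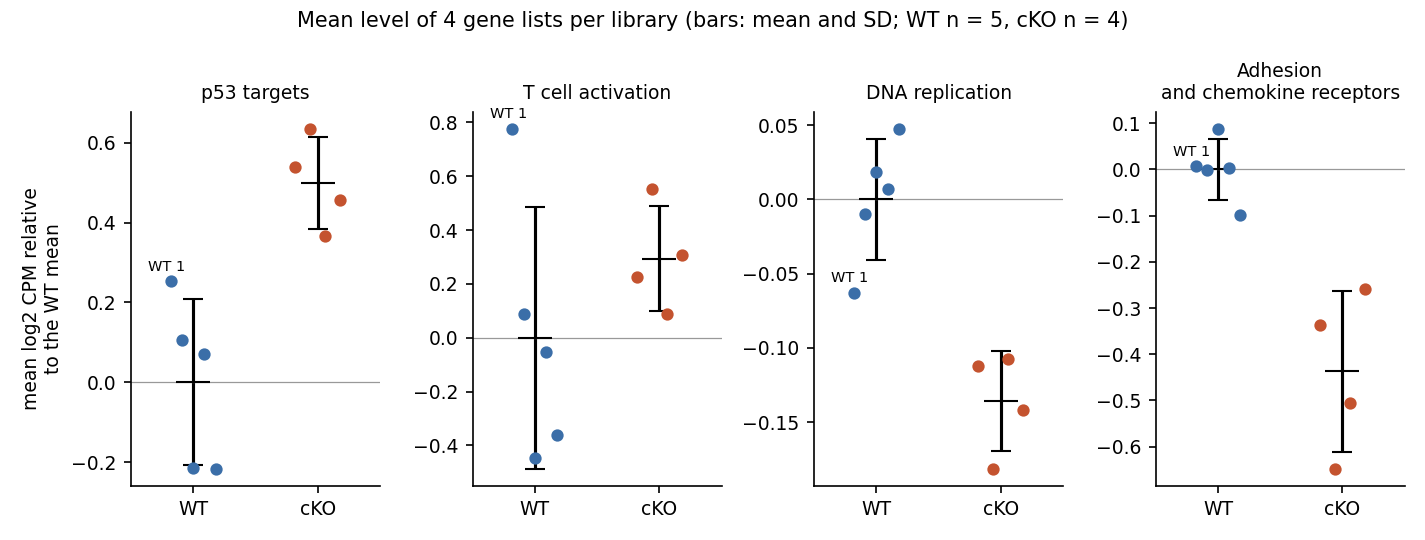
Mean log2 CPM of 4 gene lists in each library relative to the WT mean, with WT in blue (n = 5), cKO in red (n = 4) and bars for the mean and SD. WT 1 is the highest of all libraries for T cell activation genes, and the WT and cKO libraries do not overlap for the other 3 lists.

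Genes of the helper lineages changed singly, and camera called no lineage list. For Th1, 2 of 17 tested fell, in both adjustments, namely Stat4 at -0.36 and Il18r1, a chain of the IL-18 receptor, at -1.09 (SE 0.19, edgeR adjusted p = 0.00407), and camera gave adjusted p = 0.814 with a median of 0.04 and a mean of -0.03. The Th1 median was below 0 with sample weights in limma-voom (-0.01) and without any 1 of cKO 2 or 6 or WT 4, 5 or 9 (from -0.08 to -0.002), 0.01 without cKO 7, 0.09 without WT 1 and 0.07 without cKO 8. For Th2, 2 of 13 fell, and 4 fell and 1 rose adjusted over the list alone. Over all genes these were Ccr4, shared with the migration list, and Il4ra, the IL-4 receptor alpha chain, at -0.59 (adjusted p = 0.0108), with a camera adjusted p of 0.174 that was 0.0120 without cKO 2. For Th17, 1 of 10 rose and 2 fell, and 1 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.695). The IL-23 receptor gene Il23r was at -1.28 (SE 0.27), the IL-1 receptor gene Il1r1 at -1.63 (SE 0.38) and the aryl hydrocarbon receptor gene Ahr at 0.75 (SE 0.23).

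For regulatory T cells, 1 of 15 tested genes rose and 5 fell, in both adjustments. Ikzf2, the transcription factor Helios, rose by 0.46 (SE 0.06, edgeR adjusted p = 0.000651), whereas Capg was at -0.80 (adjusted p = 0.000436), the folate receptor gene Izumo1r at -0.59 and Ebi3, a subunit of the cytokines IL-27 and IL-35, at -0.67. Foxp3, which defines the lineage, was at 103 CPM in WT and 102 CPM in cKO (adjusted p = 0.953), and camera gave adjusted p = 0.383. None of 10 tested genes of follicular helper cells passed the test in edgeR in either adjustment (camera adjusted p = 0.928), the smallest p-values being those of Il6ra at -0.33 (adjusted p = 0.1004) and Sh2d1a at 0.10 (adjusted p = 0.105, and 0.0411 without WT 5). At unadjusted p under 0.05, 2 follicular helper genes were higher and 1 lower, DESeq2 and limma-voom called 0, and 1 rose without any 1 of WT 1, cKO 2 or WT 5.

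Several calls among the lineage genes changed when 1 sample was left out, and those of Stat4 and Ahr lay near the threshold (edgeR adjusted p = 0.0351 and 0.0491). In the fits that lost the call, Stat4 was between -0.38 and -0.30 and Ahr between 0.57 and 0.80. Stat4 lost its call without any 1 of WT 3, 4 or 5 or cKO 6, 7 or 8 (adjusted p from 0.0590 to 0.102) and with robust quasi-likelihood (0.0520). Ahr lost its call without any 1 of WT 3, 4, 5 or 9 or cKO 6, 7 or 8 (from 0.0701 to 0.158), with a filter of at least 1 CPM in 4 samples (0.0504), with robust quasi-likelihood (0.0879) and after GC and length offsets (0.0572), and Il1r1 without cKO 6 (0.05001). Without WT 1, 2 Th17 genes rose, and without cKO 2, 5 Th1 and 4 Th2 genes fell. Without cKO 8, 3 Th17 genes fell, and 4 of 13 tested fell in DESeq2, and 1 of 8 with a filter of at least 1 CPM in 4 samples. Among Th2 genes, 1 rose without WT 1 or cKO 7, and 3 fell without WT 9.

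Interferon-stimulated genes had a median change of 0.30 (camera adjusted p = 0.0160), with adjusted p = 0.926 with an estimated correlation and 0.388 by fry. Of 22 tested, 3 rose, 1 fell and 18 did not pass, in both adjustments. Ifih1, a sensor of viral RNA, rose by 0.53 (SE 0.08, edgeR adjusted p = 0.00245), Bst2, which encodes tetherin, was at 0.49, and Zbp1, a sensor of nucleic acids, was at -0.53. The median was 0.18 without WT 1 and 0.09 without cKO 2, and the camera call was lost without either (adjusted p = 0.177 and 0.202). The share of mitochondrial counts was 2.38% in WT and 2.59% in cKO. In this list 6 members rose without WT 5, but 1 without any 1 of cKO 2, cKO 6, WT 3, WT 4 or WT 9. Bst2 lost its call without any 1 of cKO 2 or 6 or WT 3, 4 or 9 (adjusted p from 0.0549 to 0.0739) and with robust quasi-likelihood (0.0524), and Zbp1 without any 1 of WT 4 or cKO 6 or 8 (from 0.0525 to 0.0676).

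Genes of innate sensing and NF-kB signalling went both ways. Of 17 tested, 5 fell, 1 rose and 11 did not pass, and 5 fell and 4 rose with the p-values adjusted over the list alone (camera adjusted p = 0.814). The Toll-like receptor genes Tlr1 and Tlr6 were at -0.93 (SE 0.15, edgeR adjusted p = 0.00287) and -0.78 (SE 0.20), their adaptor gene Myd88 at -0.17 (SE 0.04) and Nfkb2 at 0.63 (SE 0.17). Nfkb2 lost its call without any 1 of WT 3, 4, 5 or 9 or cKO 6 or 8 (adjusted p from 0.0543 to 0.0962) and with robust quasi-likelihood (0.0731). Tlr6 lost its call without any 1 of cKO 2, 6 or 8 (from 0.0526 to 0.0682) and Myd88 without WT 3, cKO 7 or cKO 8 (from 0.0501 to 0.0551). The list held 4 genes that rose without WT 1 and 3 without cKO 2, 4 with 1 surrogate variable or with sample weights in limma-voom, 3 of 21 tested with no count filter, 2 of 21 in DESeq2, and 2 in limma-voom, with upper-quartile scaling or after GC and length offsets. The genes that fell numbered 3 without WT 1, cKO 2 or WT 9, 2 without WT 3 or cKO 6, and 1 without cKO 8.

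Of 10 tested cytotoxic genes, 1 rose and 9 did not pass, and 3 rose with the p-values adjusted over the list alone. Klrd1, which encodes the receptor chain CD94, rose by 1.61 (SE 0.38, edgeR adjusted p = 0.0169) from 1.10 to 3.30 CPM, and camera called no shift (adjusted p = 0.132, and 0.0326 without cKO 8). Without cKO 7 or cKO 8, 2 of them rose, and 2 of 12 tested rose in DESeq2 and 3 of 12 with no count filter. The mean log2 level of the list was 1.31 in cKO 2, against 0.19 to 0.33 in the other cKO libraries. Its median change was 0.51, and 0.215 without cKO 2. Klrd1 was also highest in cKO 2, at 5.65 CPM against 2.20 to 2.93 in the other cKO libraries.

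Metabolic genes and genes of the PRC2 and MLL3/MLL4 complexes moved little. Of 16 tested glycolysis genes 1 fell, the enolase gene Eno1 at -0.19 (edgeR adjusted p = 0.0320), and of 25 genes of oxidative phosphorylation 1 fell, Cox5b at -0.17 (adjusted p = 0.0484), with none in either list adjusted over the list alone (camera adjusted p = 0.646 and 0.132, the latter 0.0474 without WT 4 and 0.0409 with no count filter), and 3 glycolysis genes fell without cKO 2. With sample weights in limma-voom, 3 genes of each list were lower. At unadjusted p under 0.05, 3 glycolysis genes and 5 of oxidative phosphorylation were lower. Both calls were lost without any 1 of WT 3, 4, 5 or 9 or cKO 6, 7 or 8, with adjusted p from 0.0559 to 0.0983 for Eno1, and from 0.0540 to 0.134 for Cox5b. Cox5b also lost it without cKO 2 (0.0545), in DESeq2 (0.0606) and limma-voom (0.0519), with DESeq2 size factors (0.0535), upper-quartile scaling (0.0734), no count filter (0.0875), 1 surrogate variable (0.0539) or no sex chromosome genes (0.0502), and after GC and length offsets (0.0694). Eno1 also lost it with upper-quartile scaling (0.0520) and, at -0.14 (SE 0.05), after the offsets (0.112). None of 18 genes of cholesterol synthesis passed in edgeR in either adjustment (1 higher and 1 lower at unadjusted p under 0.05, and 0 in DESeq2 and limma-voom; camera adjusted p = 0.996), with Hmgcs1 at 0.12 (adjusted p = 0.105, and 0.0175 without cKO 2 and 0.0422 in limma-voom with sample weights) and Nsdhl at -0.13 (adjusted p = 0.120, and 0.0227 without WT 1, where 2 of the list fell). Of 11 genes of PRC2, the complex that methylates H3K27, 2 fell in both adjustments, the histone-binding genes Rbbp7 at -0.15 and Rbbp4 at -0.12 (camera adjusted p = 0.748), and Rbbp4 lost its call without any 1 of WT 3, 4 or 9 or cKO 6, 7 or 8 (adjusted p from 0.0579 to 0.0893), with upper-quartile scaling (0.0630) and with no count filter (0.0562). Without WT 1, 1 PRC2 gene rose, and 1 did with sample weights in limma-voom. None of 9 genes of the MLL3/MLL4 complex, the H3K4 methyltransferase complex that holds Kdm6a, passed in edgeR in either adjustment (1 at unadjusted p under 0.05, and 0 in DESeq2 and limma-voom; camera adjusted p = 0.748), with Dpy30 at 0.10 and Rbbp5 at 0.03.

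Among Y-linked genes and X-linked paralogs, 3 Y-linked genes rose by small amounts and no X-linked member of the list passed. Of 7 tested, 3 rose, none fell and 4 did not pass in edgeR, in both adjustments. At unadjusted p under 0.05, 0 were lower, and DESeq2 and limma-voom called 0 lower. The median was 0.13 (camera adjusted p = 0.00545), with adjusted p = 0.327 with an estimated correlation and 0.00508 by fry. The 3 that rose were Uty, the helicase gene Ddx3y at 0.16 (edgeR adjusted p = 0.0312) and the translation factor gene Eif2s3y at 0.17 (adjusted p = 0.0352). The fourth Y-linked member, Kdm5d, was at 0.12, and the X-linked Ddx3x, Kdm5c and Eif2s3x were at 0.13, 0.08 and 0.13. Kdm6a, the X-linked paralog of Uty, stood in the demethylase list and fell by 0.55. After offsets on GC content and gene length the list was no longer called (adjusted p = 0.0559). There Ddx3y was at 0.08 (SE 0.04, adjusted p = 0.190) against 0.16 (SE 0.05) without them, and Eif2s3y at 0.09 (SE 0.05, adjusted p = 0.299) against 0.17 (SE 0.05), so that both lost their calls. The share of mitochondrial counts was 2.38% in WT and 2.59% in cKO. Ddx3y lost its call without any 1 of WT 3, 4, 5 or 9 or cKO 2, 7 or 8 (adjusted p from 0.0528 to 0.0881) and Eif2s3y without any 1 of WT 1, 3, 4 or 5 or cKO 6, 7 or 8 (from 0.0525 to 0.105), and 1 member rose without any 1 of WT 3, 4 or 5 or cKO 7 or 8.

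Markers of other cell types were mostly low, and camera called none of the 4 marker lists with at least 3 tested members (0 at unadjusted p under 0.05 with either correlation, and by fry 0 called and 1 unadjusted). Cd8b1, a chain of the CD8 coreceptor, was at 11.6 CPM in WT and 14.1 CPM in cKO (log2 0.28, edgeR adjusted p = 0.0296), and Cd8a was at 1.80 and 2.70 CPM (adjusted p = 0.217). Among 10 tested B cell markers, 1 fell in both adjustments, the antigen receptor gene Cd79b from 1.72 to 0.911 CPM, with 1 more that rose without WT 1, while Ighm was at 301 and 268 CPM (adjusted p = 0.297) and Fcer2a at 1.81 and 1.86 CPM. Among 3 tested macrophage and monocyte markers 1 fell in both adjustments, the integrin gene Itgam from 1.34 to 0.373 CPM, while Csf1r was at 14.3 and 15.5 CPM and Cd68 at 2.76 and 3.39 CPM, so that the median of the list was 0.12 and its mean -0.47. That median was 0.04 without cKO 2, 0.06 without WT 4, 0.07 without WT 5, 0.19 without WT 1 and 0.18 without cKO 7, and 0.20 with no count filter, where 8 markers were tested. Among 5 tested dendritic cell markers 1 rose in both adjustments, Cd74, the invariant chain of class II antigen presentation, from 41.6 to 58.7 CPM (adjusted p = 0.0168), with H2-Ab1 at 3.55 and 4.33 CPM. The camera adjusted p was 0.814 for B cell, 0.835 for macrophage and monocyte, 0.174 for dendritic cell and 0.695 for gamma-delta T cell markers. In the last list none of 4 tested genes passed in edgeR in either adjustment (1 at unadjusted p under 0.05, and 0 in DESeq2 and limma-voom), with Tcrg-C2 at 1.25 and 2.24 CPM (adjusted p = 0.0951, and 0.0487 without cKO 7) and Tcrg-C4 at 1.39 and 1.91 CPM.

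The plasma cell markers Sdc1, at 2.31 and 3.42 CPM (edgeR adjusted p = 0.0747, and 0.0369 without WT 1), and Igkc, at 1.17 and 1.31 CPM, did not pass over all genes, and 1 of these 2 rose adjusted over the list alone. The erythroid gene Alas2 was at 0.655 and 0.489 CPM and the endothelial gene Pecam1, which T cells also express, at 108 and 97.3 CPM, and neither passed. No natural killer or neutrophil marker had enough counts to be tested. The highest count in any library was 32 for a natural killer marker and 14 for a neutrophil marker. The neutrophil gene S100a8 had 0 counts in every library, which allows up to 0.114 CPM in the deepest and 0.146 CPM in the shallowest library for counting error only. The call of Cd8b1 was lost without any 1 of WT 3, 5 or 9 or cKO 2, 6 or 8 (adjusted p from 0.0530 to 0.0897), that of Cd74 without cKO 6 (0.0537), and Cd8a passed without WT 1 (0.0294).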

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

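The tests of shared reads, of a Y-wide rise and of Cre presence were chosen only after the results they bear on were seen, and so were the GC offsets, the level minimum for Y genes and the margin required in the GC test of Uty.

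In 12 of 214 groups of values, 1 library lay far from the others of its genotype, where chance alone gives about 10.7. Of these, 5 were low values in cKO 6 of genes that were lower in cKO. There, Eya2 was at 0.456 CPM against 1.14 to 1.25 in the other cKO libraries, Pdlim4 at 4.51 against 8.56 to 9.61, Sorcs2 at 1.78 against 2.74 to 2.93, Itgb7 at 165 against 218 to 230.5 and Tnfrsf1b at 87.8 against 96.6 to 97.8 CPM. Entpd1 was at 1.98 CPM in cKO 2 against 2.61 to 2.64, and Rbbp5 at 91.5 CPM in cKO 7 against 87.3 to 87.6. WT 1 was low for Nsdhl, at 90.6 against 102 to 106 CPM, and for Tnfrsf1a, at 31.1 against 33.1 to 33.4 CPM, and high for Cd74, at 52.1 against 37.4 to 39.8 CPM. Il18r1 was at 33.1 CPM in WT 4 against 19.9 to 21.6, and Tcrg-C2 at 1.89 CPM in WT 3 against 1.04 to 1.19.

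Chance assignment of the samples is an unlikely account of the number of called genes, though not every split was run. Among 100 of the 126 splits of the 9 samples into 4 and 5, only 1, the real one, gave at least 2324 genes. The highest other split gave 2181 genes and set WT 3, 4, 5 and 9 against the 4 cKO samples and WT 1, which points to a structure of the samples in which WT 1 stands apart from the other WT samples. WT 1 had the Kdm6a level of the WT group, 62.4 CPM, and 2933 genes were called without it.

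The rise of p53 targets in cKO was weighed against 3 explanations. A GC or length trend as the whole cause is argued against by the median change of 0.57 after the offsets, against 0.57 without them. A single library is argued against by the lowest median over the leave-one-out fits, 0.49. An effect of Cre itself, such as DNA damage, cannot be told apart from loss of Kdm6a, because 0 Cre-positive samples had an intact Kdm6a. Both therefore remain open hypotheses, while T cell activation and cell quality were not tested as explanations. Within WT, the p53 and activation lists were both highest in WT 1, at 0.25 and 0.78. Within cKO, both were highest in cKO 6, at 0.64 and 0.55. Yet WT 1 lay above every cKO sample for activation and below every cKO sample for p53 targets, which were at 0.37 to 0.64.

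The rise of Uty was weighed against 3 explanations. Reads shared with Kdm6a would lower Uty in cKO, and it rose by 0.24 (SE 0.05). A rise common to Y genes stays open, because its test depended on which genes were taken. Against all 4 other tested Y genes Uty rose more (exact permutation p = 0.0317), but without Gm20775, at 1.04 CPM in WT and excluded only after that result was seen, the remaining 3 rose by 0.15 (exact permutation p = 0.00794) and Uty did not exceed them detectably (p = 0.222). After offsets on GC content and length, Ddx3y and Eif2s3y lost their calls because their changes were smaller, at 0.08 (SE 0.04) and 0.09 (SE 0.05) against 0.16 and 0.17 (SE 0.05 for both) without them. A GC trend cannot be told apart from a change specific to Uty either, since its change was 0.15 after the offsets (adjusted p = 0.0381): this met the bound written before the result was seen, but by less than its standard error, a margin required only afterwards.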

How the results depend on the processing

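The GC and length offsets were chosen only after the data were seen. No called gene or list reversed its direction. Among values that were not called, 8 of 3 named genes changed sign, such as Kdm6b from 0.05 to -0.07 without WT 4, and so did 51 medians of 12 lists, such as PRC2 from -0.04 to 0.005 without WT 4 and regulatory T cell genes from -0.04 to 0.03 without cKO 2. Of 2028 values for 102 named genes under up to 20 other settings, 1888 kept their side of the threshold, 133 lost the call and 7 gained it, and of 504 values for 28 lists 485 kept it, 13 lost it and 6 gained it. Kdm6a stayed between -0.59 and -0.54 in all 19 of its alternatives, with adjusted p up to 0.000269.

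The number of called genes, 2324, was 242 at a fold of at least 2 (99 higher and 143 lower), and the genes higher in cKO numbered 1571 at adjusted p 0.1. Leaving out 1 sample gave from 1263 (without cKO 6) to 2933 (without WT 1) genes, from 531 to 1363 higher and from 732 to 1570 lower, part of which follows from fewer samples. The cause of the rise without WT 1 was not tested. The 7 camera calls became 0 with an estimated correlation, which widens the error of a list whose genes vary together. Fry called 6 program lists, among them the H3K27 demethylases, which camera did not call. After GC and length offsets 2087 genes were called, of which 1868 were calls without them. DESeq2 called 2539 and limma-voom 2286 genes. No paired analysis was possible because no replicate number occurs in both groups. In the simulation, changes of 1.2-fold were recovered in 32% of genes, so small changes can be missed. That share need not hold for the data, where a larger part of the genes was called than was changed in the simulation.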

Other observations

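The test of gene order was chosen only after a first count of neighbouring pairs was seen, the test of shared GC content after the other tests of neighbours, and the GC offsets and all genes named here after the data were seen.

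Of the single genes in this and the next paragraph, Entpd1 and Zap70 alone belong to a fixed list, and no group of them was tested. P2rx7, the ATP-gated channel of T cells, went from 83.8 to 28.1 CPM (log2 -1.58, SE 0.16, edgeR adjusted p = 0.000229), and Entpd1 and Nt5e, which encode the ectonucleotidases CD39 and CD73 that turn ATP into adenosine, were at -1.24 and -0.86. Art2b, an ADP-ribosyltransferase that uses extracellular NAD, was at -0.83, and Adora2a, an adenosine receptor gene, at -0.37 (adjusted p = 0.0146). Every cKO library lay below every WT library for each of these 5 genes, which were picked by their values. Thy1, the GPI-anchored T cell surface marker, went from 1048 CPM ± 117 (SD, n = 5) to 287 CPM ± 60.2 (SD, n = 4; log2 -1.87, SE 0.14, adjusted p = 3.42e-05).

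Cd80, a ligand of CD28, was at 0.97 (SE 0.15, edgeR adjusted p = 0.00215) and Tnfsf4, the ligand of OX40, at 0.82 (SE 0.15). Socs3, an inhibitor of cytokine signalling, went from 111 to 57.6 CPM (adjusted p = 0.00548) and the IL-10 receptor gene Il10ra from 65.4 to 33.4 CPM (adjusted p = 0.00192). The kinase gene Syk was at -1.62 (adjusted p = 0.00654), whereas its T cell relative Zap70 was at 235 CPM in both genotypes. Of 67 tested T cell receptor V segments, 7 fell in edgeR.

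Neighbouring genes were called in the same direction more often than in shuffled orders, a hypothesis of regional change that was found and tested on the same data. Of 14406 pairs of adjacent tested genes, 137 were both higher and 231 both lower, against 71.2 and 115 on average in 10000 orders shuffled within expression bins (permutation p = 1e-04 for both, the smallest these can give). Overlapping genes and gene families as the whole cause are argued against by the 7961 pairs at least 5000 bases apart with unlike symbols, where 77 and 115 pairs stood against 39.1 and 64.8 (permutation p = 1e-04). GC content shared by neighbours is argued against by the calls after offsets, with 57 and 97 pairs against 33.3 and 50.2 (permutation p up to 2e-04). Regional chromatin change remains an untested hypothesis, since no chromatin was measured and other shared properties of neighbours were not tested.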
